A study of Homo sapiens with 8 samples.

How the data were processed

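N6-methyladenosine (m6A) in RNA of human osteosarcoma cell lines was mapped by MeRIP-seq, in which fragmented RNA is enriched with an antibody against m6A, sequenced, and compared with sequenced RNA that was not enriched (input). Per the labels, the cell lines were U2OS and 143B, and each was infected with a lentiviral control short hairpin RNA (NC) or with a hairpin against METTL14, a subunit of the enzyme that writes m6A. The series holds 8 libraries, an input and an immunoprecipitated library for each of the 4 combinations, with 1 library of each kind per group. Groups were taken from the sample titles. Each of the 4 immunoprecipitated libraries has 1 peak list, and the 4 input libraries enter only through the values in those lists: input counts and RNA levels were not analysed here.

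Per the submitters' processing notes, FastQC 0.11.5, Trimmomatic and HISAT2 were used, with the human build hg19 (GRCh37). The peak caller, its threshold, the transcript annotation and the read depth are not given in the sources used here. Each list has 13 columns. Per the file headers, a peak has a chromosome, a start and an end, a transcript, a gene, a strand, the spliced blocks it covers, a p-value, a fold enrichment and the part of the transcript it lies in. The fold enrichment is a linear ratio made by the authors, and the p-value per peak was likewise deposited by the authors. Both were used to describe, rank or filter peaks within their own list, except in 1 alternative that counts peaks of both lists of a line at or below the median p-value of the NC list. The lists carry no counts, so the depth behind a peak is unknown. A locus is listed once for each isoform it lies in, so peaks of 1 gene are not independent of each other. Peaks that overlap on the same strand were therefore also joined to sites, and a site carries the gene name of 1 of its peaks. Coordinates are printed from 1, on hg19.

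A peak counted as shared when its spliced blocks overlapped a peak of the other list by at least 1 bp on the same strand. An NC peak with no shMETTL14 partner is called lost and an shMETTL14 peak with no NC partner is called gained; both words describe the lists and not a measured change in methylation. Shares carry exact Clopper-Pearson intervals at the 95% level, which cover counting error only and treat peaks as independent. With 1 list per group no difference has a replicate check, and no p-value was made across conditions from peaks or genes. For losses shared by both lines, U2OS NC peaks that overlap a 143B NC peak were counted when both were lost, and the number was divided by that expected from independent losses. It was also divided by the mean of 10000 shuffles of the losses within joint deciles of fold enrichment and, as an addition made after the data were seen, of the p-value.

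The comparisons, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. The 24 gene lists held 20 of fixed symbols and 4 defined by name pattern. For each list, the share of its peaks lost or gained was placed among 10000 random lists of as many genes, matched on the decile of each gene's highest fold enrichment. Matching on the lowest p-value and counting sites in place of peaks were added after the data were seen. The text always names METTL14, METTL3, MN1 and the detected m6A writers, erasers and readers. Per cell line it takes the 10 lost and the 10 gained genes with the highest fold enrichment on chromosomes 1 to 22 and X. It adds the 10 genes lost and the 10 gained in both lines by mean rank of fold enrichment, and for each NC list the 5 top genes with no peak in the other NC list. Each gene list adds up to 4 lost or gained members and 1 kept member with the highest ranks. Some genes that the rule selects were not used here. Genes chosen outside this rule are named as such. Members of near-identical families, such as GOLGA8B, DHFRL1, the ZNF genes and the ribosomal protein genes, may share reads with relatives and are uncertain.

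Alternatives changed the overlap required (50% of the shorter peak, 50% of each peak, or within 100 bp), the peaks used (the upper part of each list by fold enrichment, equal numbers, p-values at or below the NC median for the number of peaks, chromosomes 1 to 22 and X), the unit (genes, or peaks within 200 bp joined) and the use of blocks and strand. Ranking by p-value and keeping 1 transcript per gene were added later. The share of peaks with the m6A sequence motif DRACH was planned and not run, since no genome of build hg19 was used here; transcript regions come from the deposited lists. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. The overlap, the shared-loss ratio and the pair count were tested on simulated data made from the 11699 U2OS NC sites. Simulated losses of 4.86%, 19.7% and 40.7% were recovered as 4.86%, 19.7% and 40.6%, simulated shared-loss ratios of 1 and 2 were recovered as 0.968 and 2.01, and removing whole genes raised the ratio of lost pairs to 3.27. The simulated losses did not depend on p-value, and the same sites stood for both lines. The simulation therefore does not check how well matching on p-value removes shared weakness.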

Results

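The data are the m6A peak lists of 4 immunoprecipitated libraries of human osteosarcoma cells. U2OS and 143B are established osteosarcoma lines, and each has 1 list from cells with a control hairpin (NC) and 1 from cells with a hairpin against METTL14 (shMETTL14). METTL14 forms with METTL3 the complex that methylates adenosines in messenger RNA, and the series asks which m6A peaks differ between NC and shMETTL14. The U2OS NC list held 32353 peaks on 6426 genes, and the U2OS shMETTL14 list 29992 peaks on 6092 genes. The 143B NC list held 33082 peaks on 6621 genes, and the 143B shMETTL14 list 35195 peaks on 6916 genes. A locus was listed for each of its isoforms, on average 2.70 to 2.77 times, and joining these gave 11699, 10822, 12258 and 12886 sites in the same order. Read depth is unknown, since the lists carry no counts.

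METTL14 itself carried peaks in all 4 lists, which do not measure its RNA level, so the knockdown could not be checked here. In U2OS, METTL14 had 5 peaks at 3 sites with NC and 2 peaks at 2 sites with shMETTL14. The NC peaks lay in the coding sequence (chromosome 4, 119610532 to 119613138), across the stop codon (119631339 to 119631505) and in the 3' UTR (119631744 to 119631834). With shMETTL14 the peak across the stop codon was listed at a fold enrichment of 5.45, beside a 3' UTR peak at 119632222 to 119632402 with a fold enrichment of 18.5. In 143B, METTL14 had 1 peak with NC, in the 3' UTR at 119632163 to 119632342, and 4 peaks at 2 sites with shMETTL14, all in the coding sequence. METTL3 had no peak in 3 of the lists and 2 peaks in 143B shMETTL14.

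Most NC peaks on m6A writers, erasers and readers were kept in both lines, as for random lists of like p-values. Of the 105 peaks on 17 such genes in U2OS NC, 11 were lost (10.5%, interval 5.35 to 18.0), and of the 103 peaks on 16 genes in 143B NC, 9 were lost (8.74%, interval 4.07 to 15.9). Matched on p-value these shares lay at percentiles 22.3 and 52.0, with random medians of 15.5% and 8.46%. Of the shMETTL14 peaks on these genes, 10 of 105 were gained in U2OS (9.52%) and 27 of 113 in 143B (23.9%). Every one of the 20 HNRNPC peaks and of the 4 CBLL1 and 2 EIF3A peaks was kept in both lines. Lost peaks in U2OS included YTHDF1 (2 of 6), KIAA1429 (3 of 6), WTAP (1 of 3) and IGF2BP2 (1 of 10). In 143B, IGF2BP2 lost 3 of 13 peaks and RBM15 2 of 11. YTHDF2, a reader that promotes decay of methylated RNA, gained 5 peaks in each line, from 6 to 9 listed peaks in U2OS and from 3 to 8 in 143B. Joined to sites, YTHDF2 had 2 in both U2OS lists, and 1 with NC and 2 with shMETTL14 in 143B. The demethylase FTO went from 4 to 6 listed peaks in U2OS and from 0 to 3 in 143B, and ALKBH5 from 2 to 1 and from 4 to 3. FTO had 2 sites in both U2OS lists, and 0 with NC and 1 with shMETTL14 in 143B. Peaks of ZC3H13 went from 10 to 15 in U2OS and from 9 to 6 in 143B, with 0 lost or gained in either line. IGF2BP1, IGF2BP3 and ZCCHC4 had peaks only in the 143B shMETTL14 list, and YTHDC2 only in U2OS shMETTL14. METTL16, RBMX and HNRNPA2B1 differed by at most 1 listed peak between NC and shMETTL14 in either line, and YTHDF3 kept all its NC peaks in both.

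MN1, a transcriptional regulator, carried 6 peaks in U2OS NC and 1 in U2OS shMETTL14, and 1 in 143B NC and 0 in 143B shMETTL14. In U2OS, 5 of the 6 NC peaks were lost: in the 3' UTR (chromosome 22, 28146633 to 28146903), at 3 places in the coding sequence and in the 5' UTR (28196976 to 28197036). The kept peak was the strongest by the authors' p-value (5.0e-18, fold enrichment 4.27), and its shMETTL14 partner was 28192989 to 28193049. The single 143B NC peak (28196826 to 28197006, fold enrichment 14.3) overlapped the 5' UTR peak of U2OS, so this place was lost in both lines. That U2OS peak was weak, with an authors' p-value of 0.0025, where the largest in the list was 0.0055, and a fold enrichment of 2.41. For the other lost U2OS peaks the authors' p-values ran from 6.9e-08 to 0.00023. Of the 71 genes with 6 sites in U2OS NC, 3 had at most 1 site with shMETTL14, namely MN1, BRD3 and SLC26A2, and the median was 5 sites. The count was made after the values were seen, and BRD3 and SLC26A2 are named for that reason.

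**Figure D1:**
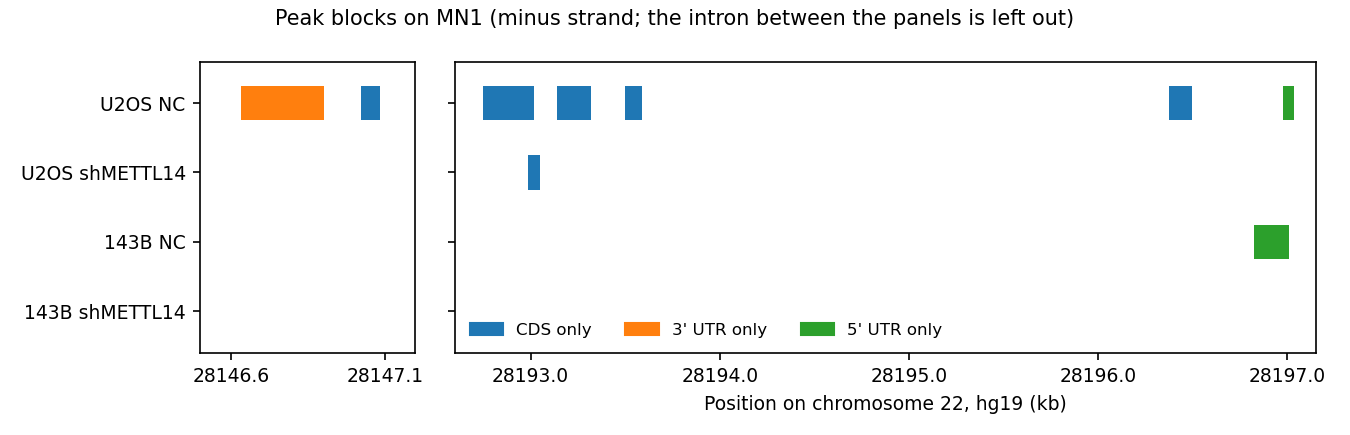
Spliced blocks of the peaks on MN1 along chromosome 22 (hg19, kb), 1 row per list, coloured by transcript region. U2OS NC holds 6 peaks, U2OS shMETTL14 1, 143B NC 1 and 143B shMETTL14 0.

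The first comparison asks whether METTL14 knockdown lowered the number of peaks. Genes with a peak went from 6426 to 6092 in U2OS and from 6621 to 6916 in 143B. The number of peaks with shMETTL14 was 0.927 times that with NC in U2OS and 1.06 times in 143B. For sites the U2OS ratio was 0.925, and in 143B the 12258 sites with NC stood against 12886 with shMETTL14. Covered length was 3.46 Mb with NC and 3.16 Mb with shMETTL14 in U2OS, and 4.22 Mb in 143B shMETTL14. The median spliced width of a peak was 210 nt in both U2OS lists, 209 nt in 143B NC and 236 nt in 143B shMETTL14. The lines thus differed in direction, with 1 list per group and no replicate check.

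In U2OS, 8688 of 32353 NC peaks were lost (26.9%, interval 26.4 to 27.3) and 6275 of 29992 shMETTL14 peaks were gained (20.9%, interval 20.5 to 21.4). At the level of genes, 1089 had peaks only with NC, 755 only with shMETTL14 and 5337 with both. The lost peaks with the highest fold enrichment were on GOLGA8B and FAIM, an inhibitor of Fas-induced apoptosis (38.5 each), and on SOX5, a transcription factor of cartilage development (29.5). Such high values are coarse, since 97.7% of the U2OS NC peaks at 20 or above lay within 0.1 steps of a whole multiple of a step of 1.28, fitted to the same values, and ties are frequent; the counts behind them are unknown. Next came CEP63 and TIFA (27.0 each), then CHRM4, TCTN1, FGF9, SYT17 and GATA4 (25.7 each). SOX5 had 8 peaks with NC and 0 with shMETTL14, FAIM 6 and 0, and TCTN1, GATA4, CHRM4, FGF9 and SYT17 also had none with shMETTL14. Gained peaks were led by MDM4, a relative of the ubiquitin ligase MDM2, and TSNAX (28.3 each), followed by MTDH and SYAP1 (26.1 each). NT5C2, the NF-kappa-B subunit REL and the Wnt receptor ROR2 followed at 25.1, and GID4, FAM171A2 and ZNF791 at 24.0. REL went from 4 to 10 listed peaks and ROR2 from 0 to 1.

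Among the gene lists in U2OS, apoptosis and survival genes had the largest lost share, 68 of 139 peaks (48.9%, interval 40.4 to 57.5). CASP8, the initiator caspase of death receptors, gave 26 of the 68, CFLAR, its inhibitor, 13, and BIRC2 and BCL2L11, both outside the naming rule, 9 and 5. Against random lists this share lay at percentile 98.2 when matched on fold enrichment and 97.6 when matched on p-value. Counted in sites, 17 of 38 were lost and the percentiles were 94.3 and 92.5, inside the central 95% of random lists. C2H2 zinc finger genes lost 567 of 1497 peaks (37.9%), with ZNF451, ZNF256, ZNF19 and ZNF28 at the top. This share lay at percentile 100 by fold enrichment and 53.8 by p-value. At the other end, adhesion and matrix genes lost 8 of 136 peaks (5.88%), with CDH2 and THBS1 among them, ribosomal protein genes 11 of 133 (8.27%), housekeeping genes 8 of 74 (10.8%) and mitochondrially encoded genes 0 of 14. Matched on fold enrichment, the adhesion and ribosomal shares lay at percentiles 0.325 and 0.19. Matched on p-value, they and the housekeeping share lay inside the central 95%, while the mitochondrially encoded genes lay at percentile 2.42, and at 0 by fold enrichment. Counted in sites, the mitochondrially encoded genes lost 0 of 11, at percentile 6.04 by p-value, inside the central 95%, and 0.08 by fold enrichment.

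Signalling lists in U2OS lay near the whole list. Lost were 38 of 128 TGF-beta and BMP peaks (29.7%), including all 5 on BMPR1B, 47 of 162 Hippo peaks (29.0%), with FAT4 going from 6 to 1, and 36 of 131 Wnt peaks (27.5%), with FZD3 going from 5 to 0. Notch genes lost 13 of 50, PI3K-AKT-mTOR genes 29 of 114 (25.4%), with INSR going from 4 to 0, and growth factor receptor and MAPK genes 17 of 70 (24.3%). Osteoblast and bone matrix genes lost 16 of 68 (23.5%). Among them RUNX2, the master regulator of osteoblasts, went from 8 to 3 listed peaks. Retinoic acid genes with MN1 lost 28 of 133 (21.1%), chromatin modifiers 96 of 464 (20.7%), cell cycle and checkpoint genes 24 of 118 (20.3%) and DNA repair genes 28 of 146 (19.2%). PALB2, a partner of BRCA2 in DNA repair, went from 3 to 0. Immediate early and widely methylated transcription factors lost 15 of 111 (13.5%), with KLF2 among them. Markers of other cell types held few peaks, with 0 of 3 lost for blood and immune markers, 4 of 28 for epithelial and neural markers, 3 of 8 for fibroblast, muscle and cartilage markers, and 1 of 3 for histone genes.

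Of gained peaks in U2OS, growth factor receptor and MAPK genes held 34 of 82 (41.5%; percentile 98.7 by fold enrichment and 96.1 by p-value). The gained peaks included those on ERBB2 (7), MET (5), SPRY2 (3) and EGFR (2), none of which had an NC peak. GRB2 gained 10 and PDGFRA 1, and all 4 NC peaks of GRB2 were lost. ERBB2 and MET are outside the naming rule. Adhesion and matrix genes gained 45 of 193 (23.3%), of which 14 lay on FN1, outside the naming rule, 9 on ITGA6 and 8 on PXN. C2H2 zinc finger genes gained 349 of 1268 (27.5%; percentile 99.8 by fold enrichment and 9.2 by p-value), apoptosis genes 21 of 80, cell cycle and checkpoint genes 24 of 112 (21.4%) and DNA repair genes 24 of 135 (17.8%). Wnt and PI3K-AKT-mTOR genes each gained 16 of 98 (16.3%), Hippo genes 23 of 142 (16.2%), osteoblast genes 11 of 68 (16.2%) and ribosomal protein genes 19 of 142 (13.4%). Lower shares were seen for Notch genes (4 of 39), TGF-beta and BMP genes (11 of 111), m6A genes (10 of 105), housekeeping genes (6 of 66), immediate early factors (9 of 106), chromatin modifiers (29 of 399) and retinoic acid genes with MN1 (8 of 129). The share of chromatin modifiers lay at percentile 0.25 by fold enrichment and 7.72 by p-value, and at 0.69 and 15.5 in sites. Marker lists gained 0 of 3 (blood and immune), 7 of 31 (epithelial and neural) and 6 of 11 (fibroblast, muscle and cartilage), histone genes 1 of 3 and mitochondrially encoded genes 0 of 14.

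In 143B, 6854 of 33082 NC peaks were lost (20.7%, interval 20.3 to 21.2) and 9615 of 35195 shMETTL14 peaks were gained (27.3%, interval 26.9 to 27.8). Genes with peaks only with NC numbered 780, those with peaks only with shMETTL14 1075, and 5841 had both. FOXO1, a transcription factor restrained by AKT, had the lost peak with the highest fold enrichment (32.6). FOXO1 had 1 peak in each 143B list, at places that do not overlap. TPGS2 and the kinase STK11 followed at 31.3, UBP1 and RNF7 at 30, DHFRL1 and INVS at 28.7, and ITPR2, GAB1 and AGAP3 at 27.4. GAB1, an adaptor of receptor tyrosine kinases, went from 9 listed peaks to 0, and ITPR2, an intracellular calcium channel, from 1 to 0. Gained peaks were led by GOLGA8B (47.6), CHP1 (39.9), LRRC57 and LIAS (38.8 each) and SUGP2 (36.6), then C2orf15 (35.5), LRRC8B, EHD2 and GNE (34.4 each) and GATAD2B (33.2). GOLGA8B, lost in U2OS, was gained in 143B.

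Osteoblast and bone matrix genes gained the largest share of the 143B lists with more than 7 peaks, 39 of 73 (53.4%, interval 41.4 to 65.2). COL12A1 gave 10 of these, BMP4 9, the vitamin D receptor VDR 9 and COL1A1 1. The share lay at percentile 99.4 by fold enrichment and 99.0 by p-value in peaks, and at 87.0 and 72.3 when 13 of 33 sites were counted. C2H2 zinc finger genes gained 637 of 1606 (39.7%; percentile 100 by fold enrichment, 94.0 by p-value), led by ZNF791, ZNF155, ZNF324 and ZNF646. PI3K-AKT-mTOR genes gained 37 of 118 (31.4%), growth factor receptor and MAPK genes 35 of 115 (30.4%), chromatin modifiers 155 of 518 (29.9%; percentile 98.3 by p-value in peaks, and inside the central 95% by p-value in sites and by fold enrichment in both), Hippo genes 41 of 140 (29.3%) and apoptosis genes 44 of 159 (27.7%). Of the apoptosis peaks, 13 lay on BCL2 and 11 on APAF1. Wnt genes gained 37 of 137 (27.0%), retinoic acid genes with MN1 32 of 123, cell cycle and checkpoint genes 28 of 110 (25.5%), m6A genes 27 of 113 (23.9%) and DNA repair genes 43 of 188 (22.9%). TGF-beta and BMP genes gained 19 of 103 (18.4%), immediate early factors 21 of 121 (17.4%), including FOSB, which went from 0 to 7, Notch genes 9 of 61 (14.8%), and adhesion and matrix genes 20 of 175 (11.4%). Housekeeping genes gained 8 of 93 (8.60%) and ribosomal protein genes 10 of 153 (6.54%; percentile 0 by fold enrichment, 1.36 by p-value, and 19.4 by p-value when 9 of 59 sites were counted).

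Lost shares in 143B were 39 of 123 for PI3K-AKT-mTOR genes (31.7%), 34 of 114 for retinoic acid genes with MN1 (29.8%) and 14 of 47 for osteoblast genes (29.8%). Wnt genes lost 22 of 128 (17.2%), and AXIN2, a feedback inhibitor of Wnt signalling, went from 5 listed peaks to 0. C2H2 zinc finger genes lost 245 of 1232 (19.9%; percentile 13.3 by fold enrichment, 0.020 by p-value), ribosomal protein genes 34 of 188 (18.1%; percentile 39.6 by fold enrichment and 96.1 by p-value, and 99.99 by p-value when 18 of 70 sites were counted), growth factor receptor and MAPK genes 18 of 103 (17.5%) and Notch genes 10 of 63 (15.9%). Losses were 13 of 87 for cell cycle and checkpoint genes (14.9%), 18 of 123 for Hippo genes (14.6%), 15 of 103 for TGF-beta and BMP genes (14.6%), 26 of 181 for adhesion and matrix genes (14.4%) and 66 of 463 for chromatin modifiers (14.3%). In the TGF-beta and BMP list, SMAD9 went from 6 to 0 and the receptor TGFBR1 from 3 to 0, and in U2OS the same genes went from 3 to 0 and from 6 to 0. MMP14, a membrane matrix metalloproteinase, lost 4 of 5 peaks in 143B and 1 of 5 in U2OS. Immediate early factors lost 16 of 126 (12.7%), DNA repair genes 19 of 173, apoptosis genes 12 of 128 (9.38%) and housekeeping genes 6 of 95 (6.32%). Marker lists held 6 peaks (blood and immune), 15 (epithelial and neural) and 2 (fibroblast, muscle and cartilage) with 0 lost, and they gained 0 of 6, 0 of 17 and 6 of 7, of which PRG4 gave 5. The share of 6 of 7 lay at percentile 95.7 by fold enrichment and 99.1 by p-value. Counted in sites, 2 of 3 were gained, at percentiles 91.0 and 95.2. Histone genes lost and gained 0 of 3, and mitochondrially encoded genes 0 of 14, which for gain was below the central 95% by both matchings in peaks. All peaks of the lists lay in coding sequence or UTRs, so the fixed list of long non-coding RNAs, with 0 members listed, could not be assessed.

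Over both lines, 92 list comparisons were made, of which nominally 4.6 would lie outside the central 95% of random lists by chance. For small lists such as blood and immune markers in U2OS, random shares ranged from 0% to 100%, so these could hardly lie outside. Lost and gained shares of a line are also linked, so 4.6 is a rough guide. In peaks, 14 lay outside when matched on fold enrichment and 8 when matched on p-value. In sites, 11 and 3 did; the 3 by p-value were C2H2 zinc finger genes gained in U2OS (percentile 1.1) and lost in 143B (percentile 0), and ribosomal protein genes lost in 143B. These depend on the matching. By fold enrichment in sites the same shares lay at percentile 99.2, in the opposite tail, at 22.8 and at 53.7.

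Whether a peak was lost went with its p-value far more than with its fold enrichment. In the quintile of NC peaks with the lowest p-values, 10 of 6470 were lost in U2OS (0.155%) and 26 of 6616 in 143B (0.393%). In the quintile with the highest p-values, 4015 of 6471 (62.0%) and 3368 of 6617 (50.9%) were lost. Ranked by fold enrichment, the top quintile lost 30.2% and 27.6%, and the bottom quintile 26.7% and 18.2%. Gained peaks went with the p-value of their own list in the same way. In U2OS shMETTL14, 52.5% of the quintile with the highest p-values and 0% of that with the lowest were gained. In 143B shMETTL14 these shares were 62.7% and 0.156%. The ranking by p-value was chosen after the data were seen.

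**Figure D2:**
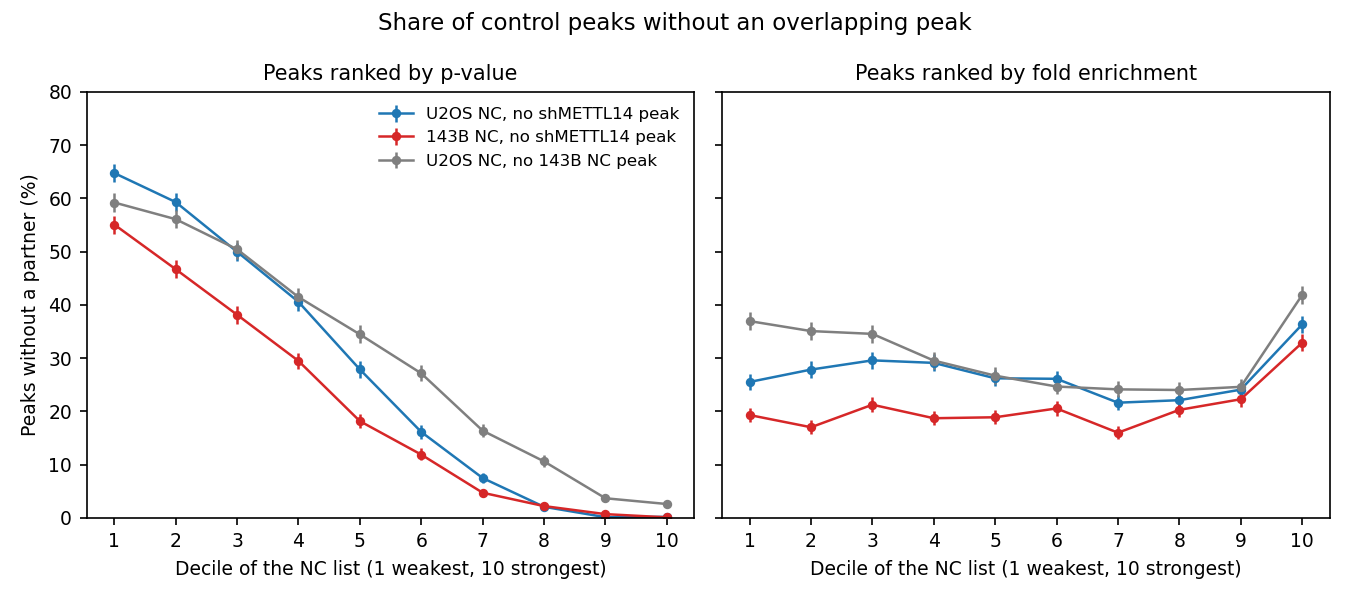
Percent of NC peaks with no overlapping peak in the other list (vertical axis), by decile of the NC list (1 weakest, 10 strongest) ranked by p-value (left) or fold enrichment (right), with exact 95% intervals. By p-value the U2OS share goes from 64.8% in the weakest decile to 0.185% in the strongest; by fold enrichment the strongest decile has 36.3%.

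By transcript region, coding sequence alone held 53.6% of U2OS NC peaks, 54.2% of U2OS shMETTL14 peaks, 50.3% of 143B NC peaks and 17591 of the 35195 143B shMETTL14 peaks. The 3' UTR alone held 22.7% and 22.4% of the U2OS peaks, and 8258 and 8816 of the 143B peaks with NC and shMETTL14. In the order of the coding shares, the stop codon region (coding sequence and 3' UTR) held 15.7%, 15.7%, 16.3% and 16.6%, and the 5' UTR alone 2.80%, 2.56%, 2.80% and 2.83%. Of the sites across the stop codon, 231 of 1772 were lost in U2OS and 194 of 1915 in 143B (10.1%). Set against the number expected from p-value deciles, the ratios were 0.874 and 0.851, and between the NC lists of the lines they were 0.835 and 0.854. Sites in the 5' UTR alone were lost more often, 200 of 441 in U2OS (45.4%) and 194 of 454 in 143B (42.7%), with ratios of 1.12 (interval 1.00 to 1.23) and 1.28 (interval 1.14 to 1.42). Between the NC lists the ratios for these sites were 1.03 and 1.11, so the U2OS ratio was close to that between control lists. Sites across the start codon had ratios of 1.22 and 1.41 for loss and of 1.06 and 0.810 for gain, against 1.13 and 1.11 between the NC lists. Expectations from p-value deciles were chosen after the data were seen.

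**Figure D3:**
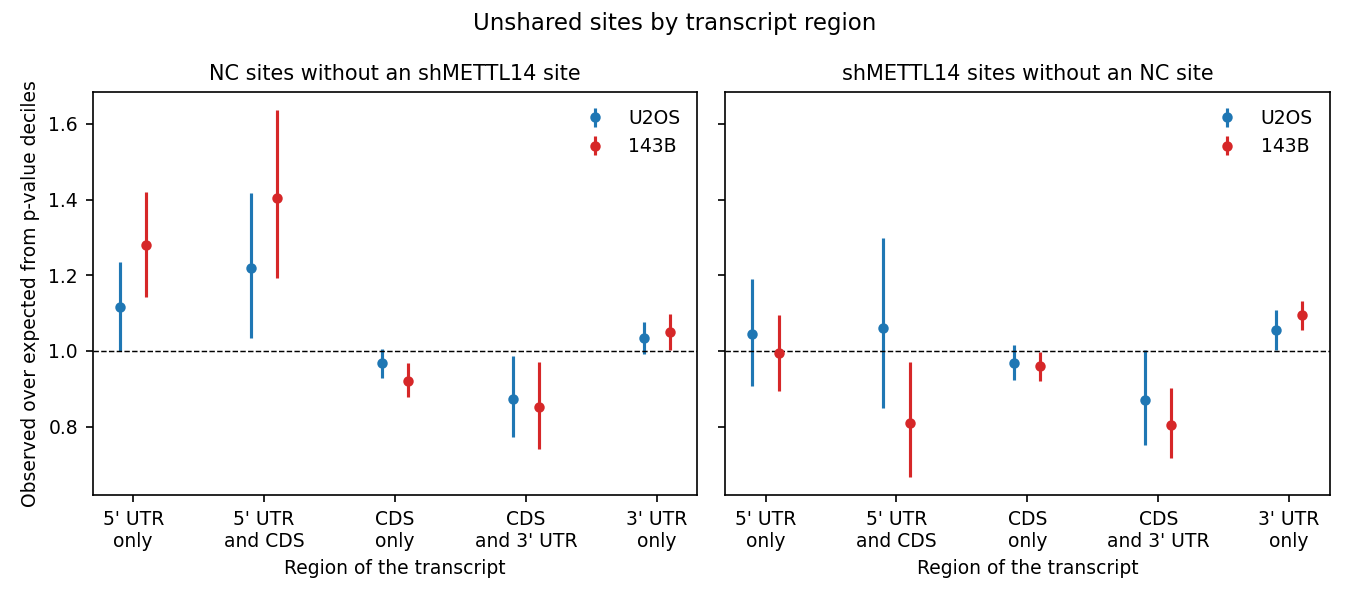
Number of lost (left) and gained (right) sites over the number expected from p-value deciles, by transcript region, for U2OS and 143B; bars are exact 95% intervals of the share divided by the expected share. Sites in the 5' UTR or across the start codon lie above 1 for loss in both lines (1.12 to 1.41), and sites across the stop codon below 1 (0.874 and 0.851).

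As a yardstick, the control lists of the 2 lines were compared. Of U2OS NC peaks, 9775 of 32353 had no 143B NC peak (30.2%, interval 29.7 to 30.7), and of 143B NC peaks 10395 of 33082 had no U2OS NC peak (31.4%, interval 30.9 to 31.9). On genes with no peak in 143B NC, the highest fold enrichments in U2OS NC were on SGPL1 (44.9), GOLGA8B (38.5), MICALCL (32.1), FAM181B (30.8) and ZNF606 (30.8). In 143B NC they were on HES7, a transcriptional repressor of the Notch pathway, and ZNF282 (41.7 each), APBB1IP and BTBD6 (37.8 each) and SMURF2 (32.6). U2OS NC peaks without a partner in 143B shMETTL14 came to 25.4%, and those without a partner in U2OS shMETTL14 to 26.9%; the 143B shMETTL14 list covers more sequence (4.22 Mb against 3.16 Mb), which by itself leaves fewer peaks unshared. In the quintile with the lowest p-values, 3.14% of U2OS NC peaks had no 143B NC peak, against 0.155% with no U2OS shMETTL14 peak.

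Peaks lost in both lines were sought among the 22578 U2OS NC peaks that overlap a 143B NC peak. Among the top by mean rank were ITPR2 (fold enrichment 16.7 in U2OS and 27.4 in 143B), VEGFB, SBF1, MC1R, ZNF180, XYLT1, NIPAL1, SPAG9 and PTGR2; 1 gene of the top 10 was not used here. ITPR2, SBF1 and XYLT1 had no peak left in either shMETTL14 list. The lost peaks of VEGFB, SBF1, MC1R and SPAG9 lay in the 5' UTR or across the start codon. VEGFB, a growth factor of the VEGF family, lost a peak across its start codon in both lines (chromosome 11, 64002070 to 64002962 in U2OS). The MC1R peak (chromosome 16, 89985450 to 89985659) is listed as 5' UTR, on a transcript that may belong to a neighbouring gene as well. Gained in both lines were peaks on SFXN1, GNE, SOWAHC, CYP51A1, PHAX, MRP63, REL, HECA, DHTKD1 and E2F3, all in the 3' UTR in both lines except E2F3. CYP51A1, an enzyme of cholesterol synthesis, had 0 peaks in both NC lists and 1 in each shMETTL14 list, and REL went from 2 to 8 listed peaks in 143B.

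In all, 1006 peaks were lost in both lines, against 302.1 expected from independent losses, a ratio of 3.33. Shuffles within joint deciles of fold enrichment gave 352.3 on average, a ratio of 2.86, and 0 of the shuffles reached 1006. Shuffles within joint deciles of p-value gave 693.5, a ratio of 1.45. For gained peaks the number was 1012, with ratios of 2.54 for independent gains, 2.08 by fold enrichment and 1.22 by p-value. Genes that had peaks in both NC lists and none in either shMETTL14 list numbered 135, against 32.9 expected from independent losses, and 119 genes had the reverse, against 32.7. These expected numbers of genes were not matched on p-value or on the number of peaks per gene. How much of the excess comes from genes with few or weak peaks is therefore unknown.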

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

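The tests on peak width and on isoforms were chosen only after the result was seen. The number of peaks with shMETTL14 was 0.927 times that with NC in U2OS and 1.06 times in 143B, opposite directions under the same hairpin design; the difference between the lines was not tested, since each group has 1 list. Genes with many isoforms do not account for it, because the ratio of joined sites was 0.925 in U2OS, on the same side of 1 as for peaks. A difference in depth of coverage could account for the higher number in 143B. Sites kept there were 1.08 times as wide with shMETTL14 as with NC in the median (interval 1.07 to 1.09). In U2OS the ratio was 0.989 (interval 0.978 to 1.00), which reaches no change, so a part of depth in the lower number there stays open. Fragment length was not measured and would also move widths. A real difference between the lines in how m6A responds, or in how far METTL14 was reduced, stays open and was not tested.

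METTL14 differed in direction between the lines, with a change in sites of -1 in U2OS and 1 in 143B. ZC3H13, a partner of the methyltransferase complex, did so as well in counts, with a change of 2 sites in U2OS and -1 in 143B. Yet 0 of its peaks were lost or gained in either line, so only the number of peaks and sites at shared places differed. These differences rest on few sites, were not tested, and come without RNA levels.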

How the results depend on the processing

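The settings that rank peaks by p-value, keep 1 transcript per gene or shuffle within p-value deciles were chosen only after the data were seen. The ratio of peak numbers stayed below 1 in U2OS (0.926 to 0.951) and above 1 in 143B (1.04 to 1.24) under every alternative run for it. It moved to 0.948 and 1.04 for genes, and to 0.951 and 1.24 for peaks at or below the median p-value of the NC list; the cause was not tested. Over all results and alternatives, 65 values moved out of the counting interval of the reported value and 24 did not; restricting to chromosomes 1 to 22 and X moved none. Shares below are percentages in the order U2OS lost, U2OS gained, 143B lost, 143B gained and U2OS NC peaks without a 143B NC peak, followed by the ratio for peaks lost in both lines where it moved. A stricter overlap raises unshared peaks by construction: 29.6%, 23.7%, 23.7%, 30.1% and 33.0% with 50% of the shorter peak, and 41.7%, 37.0%, 39.5%, 43.1% and 49.0%, ratio 2.59, with 50% of each peak. A looser overlap, within 100 bp, lowers them: 24.4%, 18.4%, 17.9%, 24.7% and 28.0%. With only the upper part of each list by fold enrichment they were 38.0%, 33.1%, 34.3%, 38.1% and 41.6%, ratio 2.46, since partners are removed. Against the whole other list the upper part gave 26.0% U2OS lost, 22.4% 143B lost, 24.1% 143B gained and 27.8% between NC lists, ratio 4.45; the cause was not tested. Equal numbers by fold enrichment gave 25.4% U2OS gained, 23.5% 143B lost and 31.2% between NC lists, since the longer list was cut and partners were removed. The ratio moved to 2.75, and the cause was not tested. Genes as units gave 16.9%, 12.4%, 11.8%, 15.5% and 19.2%, ratio 4.10, since any peak keeps a gene. Joining peaks within 200 bp gave 30.1%, 24.1%, 24.2%, 30.7% and 33.3%, ratio 2.97, and 1 transcript per gene gave 31.1%, 24.9%, 24.5%, 32.2% and 34.4%, ratio 2.92; the cause was not tested. Ignoring strand and blocks moved only 143B gained, to 26.8%, since more positions can overlap. The upper part by p-value against the whole other list gave 5.21%, 3.57%, 3.92%, 5.84% and 12.1%, ratio 11.7. Equal numbers by p-value gave 23.8%, 22.8%, 22% and 24.6% for the within-line shares. U2OS gained and 143B lost rose since partners were removed. U2OS lost and 143B gained fell since the cut took the peaks with the highest p-values from the longer list. Those peaks were unshared most often, 64.8% in the weakest decile of U2OS NC and 67.3% in that of 143B shMETTL14. Shuffles within joint deciles of p-value gave a ratio of 1.45 for peaks lost in both lines. Depth is unknown, and what it limits could not be measured. The planned share of peaks with the DRACH motif was not run.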

Other observations

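Ranked by the authors' p-value, which was chosen after the values were seen, the strongest lost peak in U2OS lay in the coding sequence of GNAI2, a G-protein alpha subunit (chromosome 3, 50294494 to 50295081, fold enrichment 15.1). GNAI2 went from 11 to 2 listed peaks in U2OS and from 10 to 3 in 143B. TEF, a transcription factor of the circadian output, went from 4 to 0 and from 2 to 0. In 143B the strongest lost peaks lay on TRIM28 (fold enrichment 5.18), which had 3 peaks in each list with no overlap, on NRP2, which went from 9 listed peaks to 0, and on PLAT, which went from 6 to 0 in 143B and from 11 to 6 in U2OS. Between the control lists, the strongest peaks on genes listed for U2OS NC and not for 143B NC were on COL1A1, SEMA3C, IGFBP5 and TENM2, the last with 31 peaks. In the other direction they were on ESM1, G0S2, ARHGAP24, RPL28 and MARCKS. Joining all 4 lists gave 18714 sites, of which 5636 (30.1%) were in every list and 7070 (37.8%) in 1 list only.

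Of the tests on lost peaks below, that on whole transcripts within a pair and that on weak peaks shared by both lines were chosen before their results were seen, and the others after. Lost peaks were weak by p-value in both lines. For genes with several sites, loss of whole transcripts between the libraries of a pair is argued against as the main source. Pairs of sites of 1 gene were lost together 0.989 times as often as in shuffles within p-value deciles in 143B (821 pairs, shuffles 739 to 963) and 1.00 times in U2OS. Genes with 1 site, the median in each list, form no pair, so the test cannot speak for them. The simulation removed whole genes whatever their p-values, so a fall in coverage that removes only weak sites was not simulated. Depletion that spares sites in the 5' UTR predicts fewer losses there, but in 143B such sites were lost at 1.28 times the number that p-value deciles predict. Between the NC lists the ratios were 1.03 and 1.11, so part of this excess may arise in any pair of lists. In U2OS the ratio was 1.12 (interval 1.00 to 1.23), too close to those between control lists to decide. In 143B, sites across the start codon were also lost at 1.41 and gained at 0.810 times the number predicted. The 143B lists thus differed along the 5' end more widely, which could hide a sparing, so the test cannot decide there either. For lost peaks, dropping out near the calling threshold and a partial loss of methylation at weak peaks cannot be told apart: that at most 0.393% of the strongest quintile was lost in either line restates the pattern and decides neither. Gained peaks were weak by p-value as well, which dropping out would give and a loss of methylation by itself would not.

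The shared loss in both lines stayed above the shuffles after matching on p-value. For sites the ratio was 1.35 in shuffles within joint deciles of p-value, with 399 observed and at most 331 in any shuffle. The p-value of 1 library per line is an imperfect measure of how weak a site is. Whether being weak in both lines accounts for the rest therefore cannot be told. Random detection is argued against by the 1431 sites found in exactly 1 list of each line. Of these, 359 were lost in both lines, against 315.3 expected, and 422 gained in both, against 378.3. Together 54.6% (interval 52.0 to 57.2) changed the same way, against 48.5% expected. Whether the coverage of whole transcripts moved alike in both lines cannot be told apart from this: 22.6% (interval 18.3 to 27.2) of the sites lost in both lay in genes without any peak left, a share that reaches across the bound set for it. Gains were shared as well (455 sites, ratio 1.21), so an effect of METTL14 on both lines and a difference between NC and shMETTL14 libraries that recurs in both may each contribute.

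Fold enrichments of 20 and above lay close to whole multiples of a step that differed by list: 1.28 in U2OS NC, 1.09 in U2OS shMETTL14, 1.30 in 143B NC and 1.11 in 143B shMETTL14. Within 0.1 of a step lay 97.7%, 94.8%, 96.3% and 92.7% of these peaks, where evenly spread values would give 20%; each step was fitted to the same values. The step was smaller with shMETTL14 in both lines.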
